A study of Mus musculus with 6 samples.

How the data were processed

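Recombinant mouse Gli protein, named Gli1 in the sample titles, was mixed with libraries of double-stranded DNA in which a few bases of a binding site were varied. Bound and unbound DNA were separated on a gel, recovered, amplified by PCR and sequenced, per the labels' protocols. The series holds 3 binding reactions, each with 1 bound and 1 unbound sample. The groups are therefore bound, with 3 samples, and unbound, with 3 samples, and each reaction was measured once.

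The authors deposited 3 tables. The values are whole-number read counts per sequence in the bound and unbound fractions, per the file headers. The authors also deposited the ratio of the bound count to the unbound count. A further column without a heading equals minus the natural log of that deposited ratio in all 2094 sequence lines, with a largest difference of 0.0005. The counts were not scaled for depth. The read counting software and its filters are not given in the sources used here. In the table of the R6 reaction, the block headings name the 4 methylation states, unmethylated, top-strand hemimethylated, duplex methylated and treated with the CpG methyltransferase M.SssI. The table of the R4-R6 reaction has an R4-R5 block and an R6 block, with no methylation state in its headings. The characteristics of its samples instead describe a library named for CTCF and R1 to R5, in conflict with the titles and block headings. The titles and headings were followed, so what its values and the placing of R6 measure rests on them. The table of 16-base sequences names neither a reaction nor a methylation state. It is called the 16-base table here and its columns were used as bound and unbound only.

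Relative binding was computed per sequence as the natural log of the bound count over the unbound count, after 0.5 was added to each count. Sequences needed at least 10 reads in each fraction. The counting standard error (SE) was the square root of the sum of the reciprocal counts. PCR reads without molecular identifiers are not independent molecules, so all SEs and intervals cover counting error only. No p-value was computed across sequences, since each reaction has 1 library per fraction.

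The change on methylation was the log ratio of a modified R6 block minus that of the unmethylated R6 block, less the median of the same difference over sequences without CpG. A sequence was called changed when its value lay outside the central 95% of sequences without CpG and exceeded 2 counting SE. Medians of CpG classes were set against 10000 random lists of the same size drawn from sequences without CpG. The planned definition counted a CpG only inside the 3 varied bases. An alternative set beforehand also counted CpG formed with the fixed bases on either side, which were inferred from the data as the report describes. Single-base variants were compared with the strongest sequence of their library, and also with the sequence holding the most frequent base at each position. Positions are counted from 1 at the first base of the 16-base sequences as listed, and a substitution gives the compared sequence's base, the position and the variant's base. The additive model was ordinary least squares of the log ratio on the base at each varied position.

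Named sequences followed a rule set before the data were examined. It took the strongest sequence of each library, its single-base variants with the highest and lowest ratio at each position, the 5 largest falls and 5 largest rises on methylation with at least 100 reads in each count, and the CpG-holding variants of the strongest sequence. Alternatives covered the pseudocount, the count minimum, centring, the width of the band, the definition of CpG, the weakest 25% of sequences, the reference sequence, the deposited ratio and weighted fits. The methylation comparison planned for the R1-R5 libraries was not made, because the 16-base table gives 1 pair of counts per sequence and no methylation state.

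The methylation calculation was tested on 100 simulated data sets of 64 sequences. Unmethylated counts followed those of the R6 reaction, and each treated sequence was given the mean read number of the M.SssI block. The simulated shift, changes and noise were set near those found in the M.SssI block. The test therefore checks the arithmetic of the calculation, and its call rates hold for those settings only. It does not cover the hemimethylated and duplex blocks. A simulated change of -2.3 at position 13 was recovered as -2.29 ± 0.04 (SD), and one of -0.8 at position 10 as -0.79 ± 0.04. In the simulations 96.6% of sequences with a CpG and 5.8% of those without were called. Computations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with figures from matplotlib 3.10.9.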

Results

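The data are read counts of DNA sequences that ran with Gli protein (bound) or without it (unbound) on a gel. Gli proteins are zinc finger transcription factors of the Hedgehog pathway, and a higher bound to unbound ratio means tighter relative binding within a reaction. The R6 reaction held 349311 bound and 183420 unbound reads over 4 blocks of 64 sequences. Its unmethylated block had 114228 bound and 40596 unbound reads, the M.SssI block 174691 and 90103, the hemimethylated block 52135 and 43448, and the duplex methylated block 8257 and 9273. The R4-R6 reaction held 774169 bound and 805024 unbound reads over 572 sequences. The 16-base table held 2101584 bound and 291875 unbound reads over 1266 sequences. No reaction was repeated, so errors below are counting SEs unless an SD is named, and differences have no replicate check.

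The R6 libraries list 3 varied bases without their neighbours, so their place in the site was found by comparison with the R4-R5 block of the same reaction. Over 64 sequences, R6 ratios matched those of 7-base sequences with C at position 10 and GAA at the end, with r = 0.996 across sequences and an SD of differences of 0.08, close to the counting SE of 0.07. With A, G or T at position 10 the correlations were 0.895, 0.893 and 0.930, and the R4 sequences lay lower by a median log ratio of -1.18, -1.13 and -1.14. R6 was therefore read as positions 11 to 13, between a fixed C at position 10 and a fixed G at position 14. Sequences are not independent replicates in these correlations.

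Gli bound unmethylated R6 sequences over a 15.2-fold range. GTT was the strongest, with a ratio of 12.3, and TCC the weakest, with 0.806. G at position 11 favoured binding, with a mean log ratio of 1.72 ± 0.64 (SD, n = 16) against 0.96 for A, 0.75 for C and 0.73 for T. C at position 12 and G at position 13 were unfavourable, with means of 0.38 ± 0.53 and 0.51 ± 0.53 (SD, n = 16 each). Against GTT, the substitution G11T lowered the ratio 4.33-fold and T12C lowered it 3.26-fold. T13G lowered it 1.68-fold, while T13C changed it by -0.03 ± 0.09, within counting error.

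In the M.SssI block, sequences with a CpG at either end of the R6 window bound less than in the unmethylated block. This comparison asks how CpG methylation at each place in the site changes binding. With neighbouring bases counted, the 11 sequences whose only CpG had its C at position 13 fell by a median 7.90-fold, a change of -2.07 ± 0.37 (SD) on the natural log scale. The 11 sequences with a CpG at position 10 fell by 2.15-fold, a change of -0.76 ± 0.20. In the 4 sequences with CpG at both positions the median fall was 22.4-fold. None of 10000 random lists of sequences without CpG had a median as low as either single-position class.

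Changes at the inner positions were smaller. The 3 sequences with CpG at position 11 fell by a median 1.25-fold, with values from -0.33 to -0.15. The 3 sequences with CpG at position 12 rose by a median 1.14-fold, with values from 0.10 to 0.21. The 30 sequences without CpG had an uncentred median change of 0.15 and an SD of 0.06, close to the counting SE of 0.06. Under this definition 33 of 34 CpG sequences were called, 31 lower and 2 higher. With CpG counted inside the 3 varied bases alone, as first planned, 3 of 8 CpG sequences were called, all higher. The 56 sequences then taken as free of CpG included those with a CpG at a junction, and their central 95% ran from -3.02 to 0.18.

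The largest falls were in sequences ending in C. After centring, GAC fell 38.9-fold (-3.66 ± 0.09), and its uncentred ratios were 11.3 unmethylated and 0.337 treated. On the same centred scale GGC fell 23.1-fold, CAC 22.0-fold, GCC 21.9-fold and CGC 21.8-fold. With neighbouring bases counted, the called rises were ACG, 1.23-fold (0.21 ± 0.06), and CCG, 1.14-fold (0.13 ± 0.06). Under the planned definition they were ACG, 1.36-fold, CCG, 1.26-fold, and TCG, 1.22-fold. Among single-base variants of GTT, all those keeping G at position 11 form a CpG with the preceding C. On M.SssI treatment GTC went from 11.9 to 0.652, while GTT went from 12.3 to 6.63 and GTA from 10.01 to 6.04. A model with 1 term per CpG position accounted for 96.5% of the variance of the change, with coefficients of -2.31 ± 0.06 at position 13, -0.80 ± 0.06 at position 10, -0.39 ± 0.11 at position 11 and 0.17 ± 0.11 at position 12 (regression SE).

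**Figure D1:**
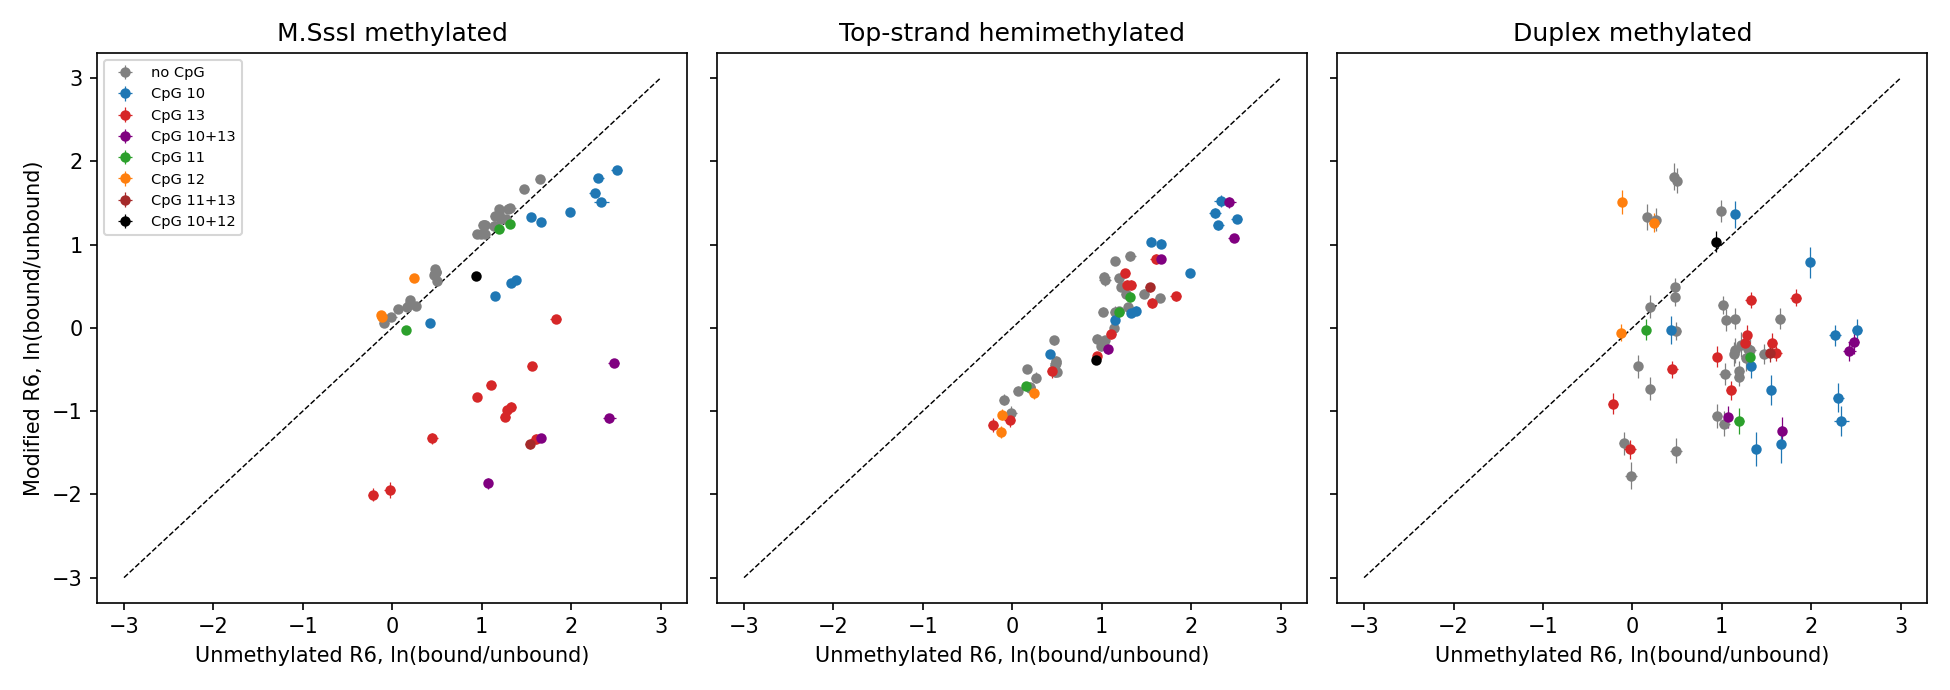
Natural log of the bound to unbound ratio for 64 R6 sequences in each modified block against the unmethylated block, coloured by the position of the CpG, with counting SEs and a dashed line of equality. In the M.SssI block sequences with a CpG at position 13 lie a median 2.07 below those without CpG, and in the hemimethylated block all sequences lie below the line.

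The hemimethylated block bound less in all 64 sequences, whether or not they held a CpG. Its median ratio was 2.59-fold below the unmethylated block, and the order of sequences was kept, with r = 0.938 and rho = 0.917 across sequences. Sequences without CpG changed by a median of -0.91, those with CpG at position 13 by -0.97, and those with CpG at position 10 by -1.06. Centred on sequences without CpG, the classes lay at -0.06 for position 13, -0.15 for position 10 and -0.21 for both. Of 10000 random lists of sequences without CpG, 1256, 10 and 109 had medians as low. These lists leave out the spread within the CpG classes. The bootstrap SEs were 0.13 for position 13, 0.14 for position 10 and 0.19 for both. No class thus lay more than 2 bootstrap SE below sequences without CpG. Under the planned definition 0 of 8 were called, and with neighbouring bases counted 7 of 34 were, all lower. The part of the shift shared by all sequences cannot be separated from the barcode or preparation of the block. The headings of the hemimethylated and duplex blocks do not name the methylated bases. Methylation of a base shared by all sequences would be removed by centring, so it cannot be separated either. The calls in both blocks take sequences without CpG as unmethylated.

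As listed, the duplex methylated block had another order of sequences from the rest. The median of its per-sequence differences from the unmethylated block was a 4.24-fold fall, with 52 sequences lower and 12 higher. Across sequences r was -0.141 and rho -0.116. With its bases read in reverse order, r with the unmethylated block was 0.633, so the sequences and positions given for this block depend on how its bases are listed. Its strongest sequence was TAG, with a ratio of 6.14, against 1.59 unmethylated. Its weakest was CCA, with 0.170, against 0.986. G as the last listed base had the highest mean log ratio here, 0.91 ± 0.66 (SD, n = 16). The M.SssI block lay above the duplex block by a median of 0.64, with an SD of 1.26. This median was 0.12 with at least 100 reads in each count and 1.07 without the weakest 25% of sequences. In addition, the duplex block lay below the hemimethylated block, at -0.51 with an SD of 1.19. The duplex block was the shallowest, with a median counting SE of 0.135 per sequence.

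The R4-R5 block of the R4-R6 reaction gave preferences over positions 10 to 16. C at position 10 and G at position 11 favoured binding in R4, with mean log ratios of 0.45 ± 0.84 and 0.48 ± 0.85 (SD, n = 64 each), against means between -0.85 and -0.67 for other bases. G at position 14 did so in R5, with 0.41 ± 0.57, against -1.07 or lower for other bases. The low ratios of G at position 13 depended on position 14. Before G, its R5 median log ratio was -0.43, against 0.44 to 0.71 for other bases (n = 16 each). Before A, C or T, G at position 13 had the highest median. Its R5 mean of -0.76 ± 0.36 (SD, n = 64) was also the highest at that position. The strongest R4 sequence was CGTTGAA, with a ratio of 8.69, and the strongest R5 sequence was AGACGAA, with 4.59. From CGTTGAA, C10G lowered the ratio 4.56-fold and G11T 6.03-fold. From AGACGAA, G14A lowered it 31.7-fold and C13G 4.08-fold, while A16T changed it by -0.07 ± 0.08. In the R6 block of this reaction the highest ratio was that of GTC, 7.57, with GTT at 7.55 and GAC at 7.45 within counting error of it.

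The 16-base table covers 5 overlapping windows of a site whose most frequent bases read GACCACCCAAGATGAA. Within this table, single-base changes lowered binding mostly in the first 9 bases. The ratio of that sequence was 35.7, and 21 of its 27 single-base variants at positions 1 to 9 were lower by more than 2 counting SE, with none higher. Positions 4 and 6 had the largest effects. C4G lowered the ratio 8.65-fold, C4A 5.84-fold, C6G 7.13-fold and C6T 5.33-fold. A5C, at -0.08 ± 0.18, and A2C, at -0.13 ± 0.16, lay within counting error, while A5G and A5T were lower, at -0.41 ± 0.12 and -0.51 ± 0.15. At positions 10 to 16 of this table, 5 of 21 variants were lower and 3 were higher, among them A10C, which raised the ratio 1.72-fold. In the R4-R6 reaction 16 of the same 21 variants were lower and 2 were higher, and the largest fall was 27.3-fold, for G11A.

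The strongest sequences differed by window. GACCACCCAAGATGAA was the strongest for positions 1 to 4 and 4 to 7, GACCACCCACGATGAA for positions 7 to 10 with a ratio of 61.3, GACCACCCACGAGGAA for positions 10 to 13 with 114 (4175 bound and 36 unbound reads), and GACCACCCAAGACGCC for positions 13 to 16 with 86.6 (1861 and 21 reads). Some variants lay within 2 counting SE of these, such as A12G in the window 10 to 13, at -0.03 ± 0.20, and C15G in the window 13 to 16, at -0.33 ± 0.25. Ratios spanned 123-fold over positions 4 to 7, 52.0-fold over 1 to 4, and 49.0-fold over 7 to 10. They spanned 6.26-fold over positions 10 to 13 and 4.91-fold over 13 to 16. Against each window's own strongest sequence, 40 distinct single-base variants were lower by more than 2 counting SE. That sequence was picked as the highest of the same window, so no variant could be higher and the direction was fixed.

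**Figure D2:**
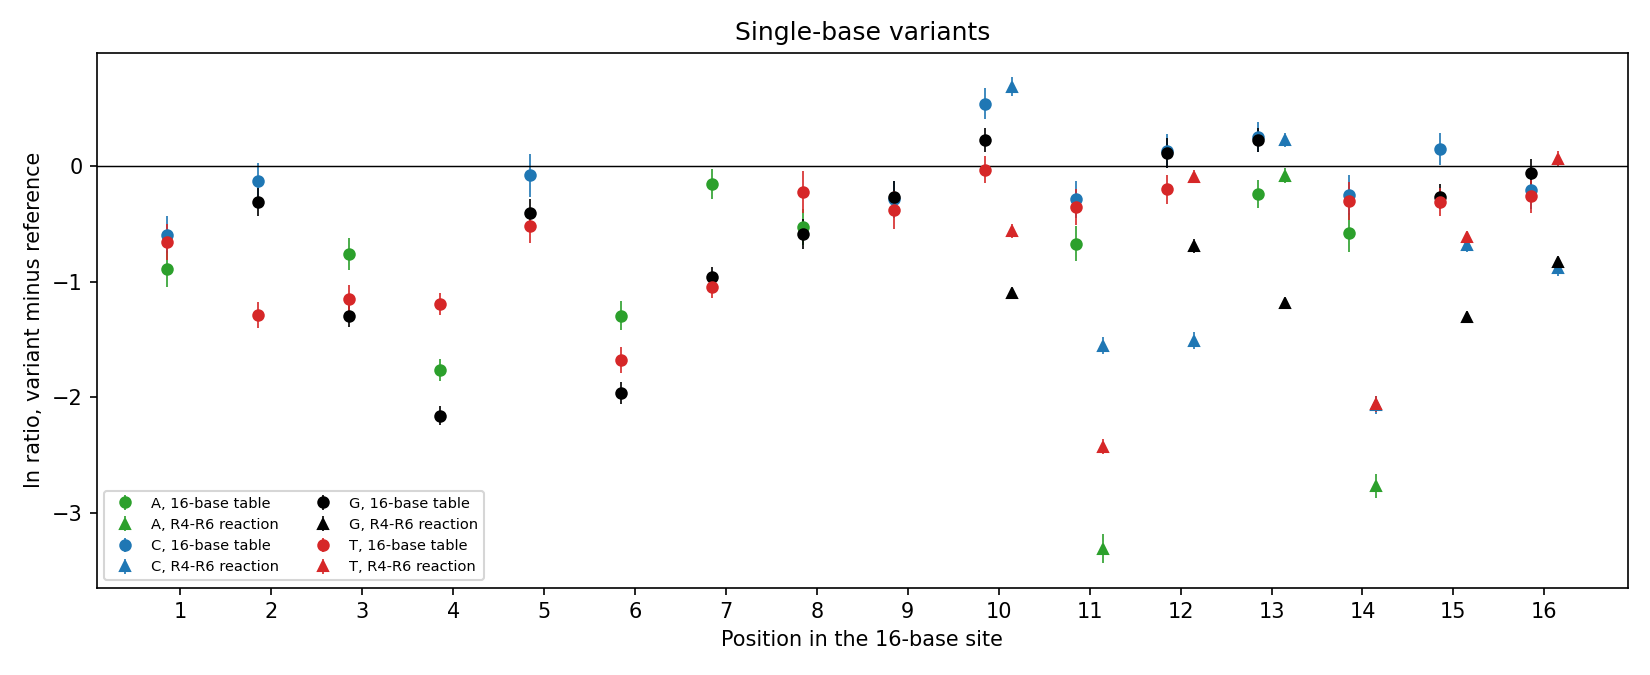
Natural log ratio of each single-base variant minus that of the most frequent sequence, by position, in the 16-base table (circles) and the R4-R6 reaction (triangles), with counting SEs. C4G, C6G, C4A and C6T are the lowest variants in the 16-base table, and G11A at -3.31 is lowest in the R4-R6 reaction.

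An additive model of base by position held most of the variation in each library. It accounted for 84.8%, 86.1% and 89.2% of the variance in the first 3 windows of the 16-base table, and for 79.6% and 72.6% in the last 2. In the R4-R6 reaction it accounted for 82.2% in R4, 81.7% in R5 and 83.3% in R6. In the R6 reaction it accounted for 84.6% of the unmethylated, 86.9% of the hemimethylated and 86.3% of the duplex methylated block. For the M.SssI block the share was 93.6%, and 95.8% with a term per CpG position. In R6, a CpG formed with a fixed neighbour is the same as G as the first varied base or C as the last. Terms for these CpGs therefore add nothing to the model, and their changes on methylation already lie within the 93.6%. The rise to 95.8% comes from the terms for CpG inside the varied bases. Residual SDs were 1.16 and 1.12 times the counting SE in the last 2 windows and 2.43 times or more elsewhere.

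The R6 library gave nearly the same order in 2 reactions. Unmethylated R6 in the R6 reaction and the R6 block of the R4-R6 reaction had r = 0.989 and rho = 0.980 across 64 sequences, with a slope of 0.81 ± 0.02. The hemimethylated block had r = 0.938 with the same block, the M.SssI block 0.217 and the duplex methylated block -0.179. The R4 and R5 sequences repeated much less closely. Over 508 sequences, the 16-base table and the R4-R6 reaction had r = 0.334 and rho = 0.317. With at least 100 reads in each count, a minimum that leaves out sequences with few unbound reads, r was 0.0401. The 64 R6 sequences of the R4-R6 reaction were also set against the 16-base table. There r was -0.035 with C at position 10, and 0.071, 0.056 and 0.060 with A, G and T. Of 21 single-base variants at positions 10 to 16, 2 went in opposite directions by more than 2 counting SE in each, while r over the 21 was 0.662. In the 16-base table the log ratio rose by 0.27 ± 0.01 per G or C over these 508 sequences, against 0.11 ± 0.04 in the R4-R6 reaction.

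**Figure D3:**
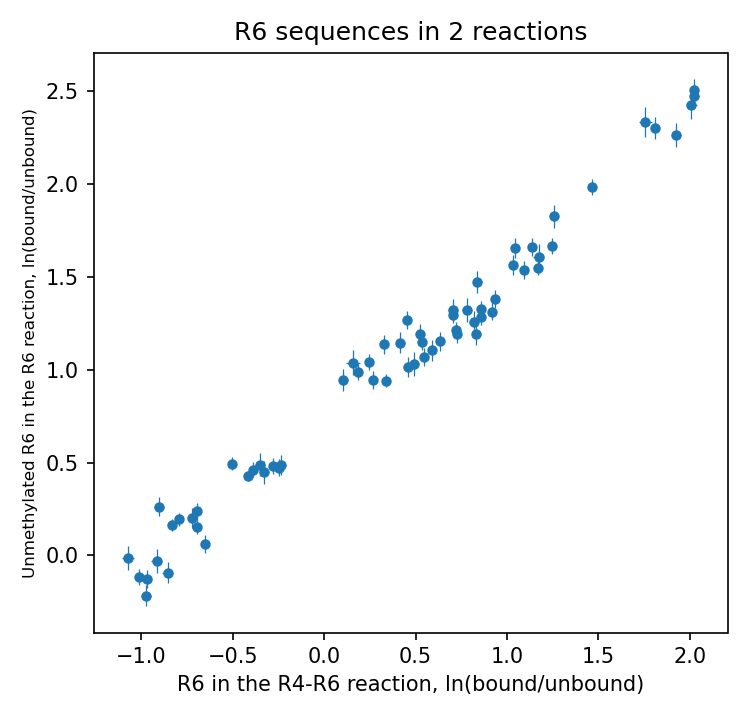
Natural log of the bound to unbound ratio of 64 R6 sequences, unmethylated in the R6 reaction against the R6 block of the R4-R6 reaction, with counting SEs. The points follow a line with a slope of 0.81 and r = 0.989.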

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

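The tests in this part were chosen after the results were seen. A pair of substitutions at positions 10 to 16 changed binding in opposite directions in the 2 tables that hold them. A10G had a log ratio of -1.10 ± 0.05 relative to the most frequent sequence in the R4-R6 reaction and 0.23 ± 0.11 in the 16-base table. T13G had -1.18 ± 0.05 and 0.22 ± 0.10. Each table comes from 1 pair of libraries, so the difference was not tested beyond counting error.

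Over positions 10 to 16 the 16-base table rises with the number of G and C, and both substitutions add a G. In this table the rises of A10G and T13G lie near the trend of 0.27 per G or C. Other variants that gain a G or C were higher, from 0.11 ± 0.13 (A12G) to 0.54 ± 0.14 (A10C), with 3 exceptions. These were A15G, A16C and A16G, at -0.26 ± 0.11, -0.21 ± 0.16 and -0.06 ± 0.12. Variants that lose a G to A or T were lower, from -0.67 ± 0.15 (G11A) to -0.30 ± 0.16 (G14T). A12C, A12G, T13C, A15C, A16C, A16G and G14T lay within 2 counting SE of 0. Variants that keep the number of G and C were also lower, from -0.31 ± 0.12 (A15T) to -0.03 ± 0.11 (A10T). Of these, only A15T lay beyond 2 counting SE. G11C and G14C, at -0.29 ± 0.16 and -0.25 ± 0.17, lay near G11T and G14T, at -0.35 ± 0.15 and -0.30 ± 0.16. The falls of G11T and G14T are thus not separated from falls without a change in G and C. The trend has the sign of most variants that gain a G or C, but not of A15G, and it does not account for A15T. Counting error is far too small for the trend, since the difference between 4 and 0 such bases at positions 10 to 13 was 24.1 times its counting SE. A binding preference of the protein as measured in the R4-R6 reaction does not account for it either. The slope stayed at 0.263 per G or C once the ratio in that reaction was taken into account, against 0.271 without it. Recovery of DNA that depends on G and C in all sequences would also appear in the first 3 windows among sequences that keep none of the 4 reference bases. There the slopes were 0.082 ± 0.025, -0.0117 ± 0.030 and 0.053 ± 0.094 (regression SE). The second lies below the bound of 0.05 by just over 2 SE, but preferences in those windows were not removed. Mean log ratios at position 7 were 2.61 for A, 1.23 for G and 1.40 for T in the window 7 to 10. In the window 4 to 7 they were 0.44, -0.23 and -0.28. At position 4 of the window 1 to 4, G was the highest of these bases, with 0.44 against 0.21 for A and 0.37 for T. With the reference C left out, G is the only G or C at these positions, so binding can shift the slopes either way. The slopes cannot decide whether recovery depends on G and C. Counting error and the preference measured in the R4-R6 reaction thus do not account for the trend, while recovery that depends on G and C stays open. Another protein concentration, an effect limited to some libraries or an unstated methylation state of the 16-base table was not tested.

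The fall of M.SssI-treated R6 sequences with a CpG at position 10 or 13 was weighed against technical causes. A general effect of the enzyme or barcode would lower sequences without CpG too, and these changed by a median of 0.148. Compression of high ratios would give a falling trend among sequences without CpG, where the slope was 0.00897. Their unmethylated ratios went no higher than 5.23 (ATT), while those with CpG at position 10 reached 12.3 (GTT). Compression above 5.23 was therefore not tested. Base composition alone would separate the same classes in the hemimethylated block. There the difference from no CpG was -0.0601 ± 0.133 (bootstrap SE) for position 13, against -2.07 on M.SssI treatment. For position 10 it was -0.148 ± 0.137, against -0.76, which leaves a share of that fall from base composition open. A lower affinity of Gli for sites methylated at position 13 is consistent with these values, as a hypothesis found and tested on the same data from 1 reaction.

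The duplex methylated block did not follow the other blocks. Counting error is too small, since the SD of its change was 7.89 times the counting SE. Reads assigned from the other blocks would bring their order with them. The correlation with the unmethylated block was -0.141 as listed but 0.633 in reverse order, so such reads are not excluded while the listing is in doubt. The bases of this block may be listed in another order. Among 12 readings tried, the order 312 of the listed bases had the highest correlation with the unmethylated block, 0.673, and reversal was next. Reversed, the 48 sequences that change on reversal had r = 0.667 with the unmethylated block, against -0.267 as listed. The 16 sequences that read the same in both directions had r = 0.477, between the bounds set for and against a reversed listing, so a reversed listing cannot be told apart from an effect of methylation with so few sequences.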

How the results depend on the processing

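Of 272 recomputed values, 216 moved by no more than 0.5 of the width of the 95% counting interval from 200 resamples, or stayed within 1.5 times for counts. Removing the G and C trend, reading the duplex block in reverse and using the most frequent bases as reference were chosen after seeing the data. Resampling adds counting noise, and 3 reported values lie above their intervals, namely the additive model's shares at positions 10 to 13 and 13 to 16 and the correlation of unmethylated R6 between reactions. Pseudocounts of 1 or none moved no result outside that range, nor did the 99% band or the deposited ratio. Causes were not tested unless stated.

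Counting CpG with the fixed neighbours raised the called sequences from 3 to 33 in the M.SssI block, from 1 to 13 in the duplex block and from 0 to 7 in the hemimethylated block. This definition changes both the sequences that hold a CpG and the band of those without. Among the 8 sequences with a CpG inside the varied bases, calls went from 3 to 7, from 1 to 2 and from 0 to 1. Without the weakest 25% of sequences, the planned definition gave 0 for M.SssI and 0 for duplex, while the definition with fixed neighbours gave 26 for M.SssI. Without centring, the median changes were -0.62 at position 10, -0.072 at 11, 0.28 at 12 and -1.92 at 13, which differ from the reported ones by the shift of sequences without CpG. Without the weakest 25% the change at position 13 was -2.32.

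Without the weakest 25%, the median differences were -0.996 for hemimethylated minus unmethylated, -1.65 for duplex minus unmethylated, -0.14 for M.SssI minus unmethylated (0.02 with all sequences, whose counting interval includes 0), 1.07 for M.SssI minus duplex and -0.72 for duplex minus hemimethylated. With at least 100 reads per count the last 2 were 0.12 and -0.36.

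The correlation at positions 10 to 16 between the 16-base table and the R4-R6 reaction was 0.395 with the G and C trend removed and 0.0401 with at least 100 reads, a minimum that leaves out sequences with few unbound reads. Read in reverse, the duplex block had r = 0.633 with R6 of the R4-R6 reaction, against -0.179 as listed, a change of sign. With the most bound sequence as reference, 7 variants in the 16-base table and 18 in the R4-R6 reaction were lower, against 40 and 29. With the most frequent bases as reference, 26 in the 16-base table were.

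The additive model's share of variance fell without the weakest 25% to 82.1%, 84.9%, 85.1%, 70.9% and 63.1% in the 5 windows, 75.8% in R4 and 80.2% in R6 of the R4-R6 reaction, and 80.0%, 79.5%, 81.4% and 78.2% in the unmethylated, hemimethylated, duplex and M.SssI blocks. Weighted fits gave 79.7%, 83.4% and 87.1% in the first 3 windows, 77.9%, 76.1% and 78.4% in R4, R5 and R6 of the R4-R6 reaction, and 79.3%, 83.5% and 88.6% in the unmethylated, hemimethylated and M.SssI blocks. With at least 100 reads it was 82.3%, 83.4%, 86.7%, 94.8% and 82.2% in the 5 windows, 82.8% in R4 and 73.6% in the duplex block.

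The methylation effect in the R1-R5 libraries and its alternatives, leaving out each library included, were not run, as no methylation state is given. Leaving out a reaction was not run either, since each value comes from 1 reaction or 1 pair. No paired analysis was possible because the result comes from no test across samples.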

Other observations

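The 4 sequences with CpG at both positions 10 and 13 had a median change of -3.11 on M.SssI treatment, against a sum of -2.83 from the medians of the single-position classes.

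The 16-base table also lists 2 sequences outside the 5 windows, each with an unbound count of 1.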
